A study of Mus musculus with 16 samples.

How the data were processed

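Whole lungs of newborn BALB/c mice, an inbred laboratory strain, were profiled on 16 arrays, 1 per mouse. Pups aged 3 days breathed ozone at 1000 ppb or filtered air for 3 h, and lungs were taken 6 h or 24 h after the exposure ended, which gives 4 groups of 4. Per the labels, the time points were run separately, each with its own air littermates, and total RNA was labelled with Cy3 from an oligo(dT) primer.

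The deposited scanner files hold spot intensity values of 1 colour on a linear scale, written by Agilent Feature Extraction, which the submitters' processing notes name and whose version 10.7.1.1 is given per the file headers. Per the file headers, the processed intensity had its background subtracted and spatial trends removed, and it was not scaled between arrays. The same deposited files carry other values, namely flags for spots well above background, saturated spots and spots of uneven signal. The authors also deposited a table of log2 values whose scale was found here by setting each column against the scanner signal of its array. Within each time point the sorted values of its 8 arrays were equal to within 0.001 for at least 99.98% of probes, with medians of 6.41 at 6 h and 6.73 at 24 h, so the 2 time points were normalized apart. How the background was treated in that table is not given in the sources used here. It was used only as an alternative. Probe positions are those of the array design on mouse build mm9.

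Spots of 1 probe were averaged after leaving out control spots and spots of uneven signal. The main values were log2 of the processed signal minus the 75th percentile of each array over its 41174 probes that are not controls. No spot was saturated. Probes well above background on at least 4 of the 16 arrays were kept (32343), and 157 probes with an uneven spot on some array were left out. Of several probes of a gene, the one with the highest mean over all arrays was used, which left 21631 genes, 7336 of them with several probes. Names were taken from a reference table through the accession for 25097 probes, the symbol for 6333 and a synonym for 1640. The name in the files was kept for 8104. Some families, such as the Cyp2a, Cyp2b and Gsta genes, hold near copies to which 1 probe can bind, so values of their members are uncertain as to which copy they measure.

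Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), with 1 mean per group over all 16 arrays. The contrasts were ozone minus air at 6 h, ozone minus air at 24 h, and the difference of these effects, 24 h minus 6 h. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. All adjusted p-values of genes are from limma and are two-sided. Errors of fold changes are standard errors (SE) with 4 arrays per group. The number of arrays limits the precision, and the median SE over all genes was 0.13 on the log2 scale. Overlaps of called genes were tested with Fisher's exact test, which treats genes as independent. The set test fry was also run at 24 h on the genes called at 6 h, per direction.

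A total of 33 gene lists, of pathways, lung cell types and tissues near the lung, were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera asks whether a list moved relative to all other genes. It was repeated with a correlation estimated from the data, and fry was run on the same lists. Fry asks whether the genes of a list moved, without setting them against other genes. Counts adjusted over the list alone correct only for the members of that list. The design, the lists, the rule for naming genes and the alternatives were fixed before the data were examined. Per ozone contrast the rule took the 10 largest rises and 10 largest falls among called genes whose 4 ozone values all lay on 1 side of the 4 air values and that were well above background on all 4 arrays of the higher group. For the difference between times it took 5 per direction, and for each list and contrast up to 4 members with the smallest p. Clone and predicted names were passed over, and some genes that the rule takes are not reported singly here. Where a probe was not well above background on 1 or more arrays of a group, the number of arrays is given. Where it was so on no array of a group, the fold is a bound, the mean of the brighter group against the mean, per array, of the higher of the dim probe's own value and the lowest signal among probes well above background.

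The fit was tested on simulated data with the spreads of these 21631 genes and, per contrast, 100 genes changed 1.5-fold and 100 changed 2-fold. At 6 h it recovered 51% of genes changed 1.5-fold and 64% of those changed 2-fold, where the genes' spreads allow 46.2% and 66.2%. At 24 h it recovered 53% and 68%, where the spreads allow 50.8% and 69.7%. Of the calls, 4.17% at 6 h and 4.23% at 24 h were false. The simulated noise was independent between genes and held no slide effect or deviating array, so that false share need not carry over to the real data. A first form of that test had required recovery above 80% of the 2-fold genes, a guess made before it was run, and failed. The missed genes had large spreads, so the requirement was replaced, after that result was seen, by the recovery that the spreads allow.

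Alternatives covered the background correction (normexp with an offset of 50), quantile normalization, the authors' log2 values, the filter, the mean of probes, array weights, the slide or the replicate number as a block, each slide and each time point alone, Xist as a covariate, other thresholds, and leaving out each array. Arrays lay on 4 slides, 2 per time point, each with 2 ozone and 2 air arrays. Scan days separated the time points, so day and time cannot be told apart, whereas each ozone contrast lies within 1 day. The sex of each pup, which the labels do not give, was read from Xist and Ddx3y.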

Results

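Gene expression was measured in whole lungs of 16 newborn mice to ask how the lung responds 6 h and 24 h after a single 3 h exposure to ozone at 1000 ppb, an air pollutant that oxidizes the airway lining. Each time point had 4 ozone and 4 filtered air lungs. The 75th percentile of the processed signal lay between 605 and 999 per array, and 65.0% to 83.9% of spots were well above background. The highest share belonged to ozone replicate 3 of 6 h, and the other arrays of 6 h had at most 72.4%. Correlations of arrays within a group across genes, which are not independent replicates, were lowest among the ozone arrays of 6 h (r = 0.969). Males numbered 2 of 4 in the ozone group and 1 of 4 in the air group at 6 h, and 3 of 4 and 1 of 4 at 24 h.

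At 6 h after exposure, genes of DNA replication were lower in the ozone lungs, though the call of the list was lost with adjusted p = 0.0812 with an estimated correlation. Of 21631 genes, 295 rose and 673 fell, and 39 of the 42 genes of the DNA replication and S phase list fell, with a list median of -0.64 on the log2 scale. The largest rise among genes well above background in all lungs of 6 h was that of Cxcl5, a neutrophil-attracting chemokine of epithelial cells, by 2.21 ± 0.34 (log2, SE, n = 4 per group, adjusted p = 0.00299). Its value ranged from 1.149 to 2.765 over the alternatives and the fits that left out 1 array. Among called genes ranked by the naming rule, whose ozone values all lay below the air values, the largest fall was that of Sct, which encodes the hormone secretin, at -1.18 ± 0.19 (adjusted p = 0.00352).

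Among replication genes, Gins1, a subunit of the replicative helicase, fell by 0.98 ± 0.12, Gins2 by 0.86 ± 0.11, and Pcna, the sliding clamp of DNA polymerases, by 0.80 ± 0.09 (adjusted p between 0.000438 and 0.000788). The Pcna probe lies on chromosome 2 from 132075420 to 132075557 (mm9). Of the 42 members, 40 fell when adjusted over the list alone. Camera gave an adjusted p of 8.69e-48 for the list, and the call was lost with adjusted p = 0.0812 with an estimated correlation. Fry, which does not set the list against other genes, gave an adjusted p of 0.000308. The list mean was -0.70 within the first slide and -0.53 within the other, and 38 members fell with slide as a block. Dscc1, a factor of sister chromatid cohesion, fell by 1.14 ± 0.11, Chek1, a kinase of the replication checkpoint, by 0.96 ± 0.15, Lrr1 by 0.92 ± 0.15, and Ccne2, an S phase cyclin, by 1.06 ± 0.21. The mitosis list, by contrast, had 6 of 45 members lower (9 adjusted over the list alone) and a median of -0.21. They included Cdk1 at -0.65 ± 0.11, whose other probe had the opposite sign, and Mad2l1 at -0.57 ± 0.11. Its camera adjusted p was 2.19e-07, and adjusted p = 0.904 with an estimated correlation.

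Of 47 cytokine and chemokine genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone), and the list as a whole was not called (camera adjusted p = 0.907). Besides Cxcl5, on chromosome 5 from 91190205 to 91190264 (mm9), Ccl20, a chemokine of airway epithelium, rose by 1.86 ± 0.41 and Ccl11, the eosinophil chemokine eotaxin, fell by 0.99 ± 0.23. Ccl20 was no longer called without ozone replicate 1, ozone replicate 2 or air replicate 4 of 6 h. Ccl11 was no longer called without ozone replicate 1, ozone replicate 2 or air replicate 3 of 6 h. Despite the rise of Cxcl5, none of 29 neutrophil genes was called at 6 h, over all genes or adjusted over the list alone. The neutrophil list had a median of 0.15 and a camera adjusted p of 0.223. In the acute phase and STAT3 list 5 of 35 members rose and none fell (9 rose and 2 fell adjusted over the list alone). Lrg1, a secreted acute phase glycoprotein, rose by 0.76 ± 0.10 and Cd14, a co-receptor for bacterial lipopolysaccharide, by 0.44 ± 0.09. The list had a camera adjusted p of 0.0127, and adjusted p = 0.732 with an estimated correlation. The call was also lost with normexp (adjusted p = 0.0719), with the mean of probes (adjusted p = 0.0618) and in the slide of replicates 3 and 4 (adjusted p = 0.0863). Pigr, the receptor that carries antibodies across epithelium, was well above background on 3 of 4 ozone arrays and no air array, and was at least 2.18-fold higher in ozone in the main fit (adjusted p = 0.0027). Its log2 value ranged from 0.643 to 2.739 over the alternatives and the fits that left out 1 array. The gene was called in 9 of 12 alternatives and in all 16 of those fits. It was the 1 member of 27 in the mucous secretory list that was called.

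In the NRF2 and antioxidant list 3 of 47 members rose and 2 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.359). Osgin1 rose by 0.75 ± 0.10 and Gpx2, a glutathione peroxidase of epithelium, by 0.66 ± 0.12, whereas Prdx1, a peroxiredoxin, fell by 0.48 ± 0.11. The heat shock and unfolded protein list was mixed, with 3 members higher and 8 lower of 39 (3 and 11 adjusted over the list alone). Hspa1a, a cytosolic chaperone, rose by 0.67 ± 0.12, and Hspa5 and Pdia6, which act in the endoplasmic reticulum, fell by 0.51 ± 0.09 and 0.48 ± 0.09. Its camera adjusted p was 0.000304, and adjusted p = 0.732 with an estimated correlation and 0.0851 with quantile normalization. The list mean was -0.17 in the slide of replicates 1 and 2 and -0.06 in the other (adjusted p = 0.0553). In the cholesterol synthesis list 4 of 27 members fell (11 adjusted over the list alone), namely Msmo1 by 0.57 ± 0.10, Idi1, Cyp51 and Sc5d, with a camera adjusted p of 1.05e-06 and adjusted p = 0.732 with an estimated correlation. The mean of that list was -0.39 in the slide of replicates 1 and 2 and only -0.06 in the other, where it was not called (adjusted p = 0.142). Sc5d was called in 11 of the 16 fits that left out 1 array, Cyp51 in 12 and Idi1 in 14. The interferon-stimulated list had 2 of 46 members lower (2 adjusted over the list alone), Ifi27 at -0.63 ± 0.10 and Oas1a (called in 3 of the 16 fits), and a camera adjusted p of 0.00117 (adjusted p = 0.904 with an estimated correlation). It was no longer called without ozone replicate 3 of 6 h (adjusted p = 0.133). Its mean was -0.04 in the slide of replicates 1 and 2 (adjusted p = 0.703) and -0.31 in the other. The ciliated cell list had 2 of 37 lower (2 adjusted over the list alone), Mlf1 and Sntn (called in 11 and 5 of the 16 fits), with a camera adjusted p of 0.0074 (adjusted p = 0.904 with an estimated correlation). Its mean of -0.05 was 0.02 in the slide of replicates 3 and 4 and 0.01 without ozone replicate 2 of 6 h. Of the oesophagus and squamous epithelium list, 1 of 17 members, Dmkn (called in 6 of the 16 fits), fell and none rose (6 rose and 1 fell adjusted over the list alone), while its median was 0.54 (camera adjusted p = 0.00384, adjusted p = 0.811 with an estimated correlation, 0.0946 in the slide of replicates 1 and 2).

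Other genes with large changes at 6 h were Gdpd2 (1.09 ± 0.18), Col25a1, a transmembrane collagen (1.04 ± 0.12), Atp6v0a4, a proton pump subunit (1.19 ± 0.23), Lhfpl3, Pla1a and Gpr182, which rose, and Spp1, which encodes osteopontin (-0.88 ± 0.18), which fell. Xrra1 (well above background on 2 of 4 air arrays), Mslnl, Tmem82 and Ankrd1 were also among the largest changes, and each lost its call without at least 1 array, Mslnl in all but 2 of the 16 fits. Thsd7b was not well above background on any ozone array and was at least 1.48-fold lower (adjusted p = 0.0277), but its other 2 probes had the opposite sign, and its value was 0.12 with normexp and 0.15 for the mean of probes. Elastin (Eln) was higher by 0.63 ± 0.15 and versican (Vcan, 1 of whose 3 other probes had the opposite sign) was at -0.68 ± 0.10, 1 rise and 1 fall among 49 matrix genes (4 and 2 adjusted over the list alone, camera adjusted p = 0.0834).

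Of the 66 genes taken by the naming rule and called at 6 h, 31 were called in every fit that left out 1 array. The count of 968 genes was 487 without ozone replicate 1, 522 without ozone replicate 2, 433 without ozone replicate 3, 621 without air replicate 1, 1690 without air replicate 2 and 196 without air replicate 4 of 6 h, 100 when only the arrays of 6 h were fitted, 558 with Xist as a covariate and 1814 with array weights. With normexp 152 rose and 801 fell. With slide as a block 876 genes were called, and 53 and 760 within the slides. Of the 16 fits that left out 1 array, Ankrd1 was called in 10, Top2a, Tmem82 and Thsd7b in 11, Prdx1 and Eln in 13, and Ccne2, Cd14 and Xrra1 in 15.

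**Figure D1:**
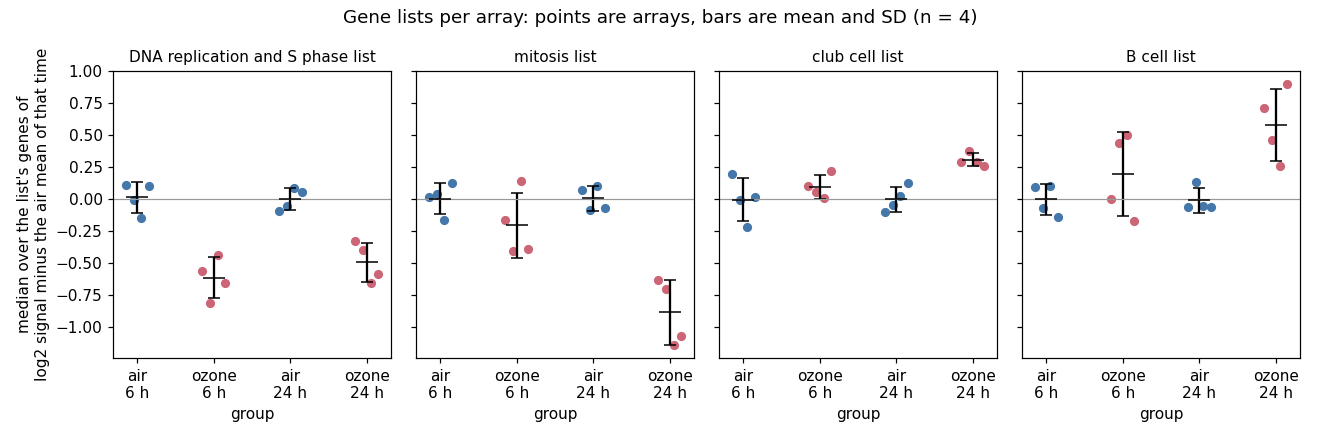
Median over each list's genes of the log2 signal minus the air mean of the same time, per array (points), with the mean and SD of each group of 4. The replication list was lower in ozone at both times, and the mitosis list had a median fold change of -0.90 at 24 h and -0.21 at 6 h.

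At 24 h after exposure, genes of mitosis were lower in the ozone lungs. Of the genes of club cells, the secretory cells of the small airways, 6 of 29 were higher, and of B cell genes 5 of 19. The calls of these lists were lost with adjusted p = 0.0947 and adjusted p = 0.213 with an estimated correlation. In all, 149 genes rose and 286 fell. Of 45 mitosis genes 44 fell, with a median of -0.90. The largest rise among called genes ranked by the naming rule was that of Inmt, an N-methyltransferase, by 1.98 ± 0.27 (log2, SE, n = 4 per group, adjusted p = 0.000667), on chromosome 6 from 55120770 to 55120829 (mm9).

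The mitosis list held its call with the preset correlation (camera adjusted p = 1.08e-84) and with an estimated one (adjusted p = 0.0211 with an estimated correlation), and all 45 members fell when adjusted over the list alone. Top2a, a DNA topoisomerase of dividing cells, fell by 1.13 ± 0.13, Bub1b, of the spindle checkpoint, by 1.11 ± 0.13, and Hmmr by 1.24 ± 0.19. Cyclin A2 (Ccna2) fell by 0.98 ± 0.10 and Cdk1 by 0.97 ± 0.11. Other genes of the spindle or of chromosome division among the largest falls were Kif15, Kif18b, Depdc1a, Ttk and Dlgap5, between -1.19 and -1.05, and Polq, a DNA polymerase of break repair, fell by 1.07 ± 0.18. The list mean was -0.69 in the slide of replicates 1 and 2 and -1.09 in the other, and 43 members fell with slide as a block. The replication list had 26 of 42 members lower (40 adjusted over the list alone), a median of -0.51, a camera adjusted p of 3.48e-51 and adjusted p = 0.0325 with an estimated correlation. Rrm2, a ribonucleotide reductase subunit, fell by 0.84 ± 0.10 and Uhrf1 by 0.69 ± 0.11.

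In the club cell list 6 of 29 members rose and none fell (12 adjusted over the list alone), with a median of 0.30, a camera adjusted p of 6.01e-14 and adjusted p = 0.0947 with an estimated correlation. Its fry adjusted p was 0.00407. The cytochrome P450 gene Cyp2a5 rose by 1.58 ± 0.23, the carboxylesterase Ces1d by 0.56 ± 0.08 and Aldh1a1 by 0.52 ± 0.09. Cyp2a4 (1.57 ± 0.28) and Cyp2b9 (0.96 ± 0.12) were also among the largest rises, but a probe of these families can bind near copies. The same holds for Gsta1, Gsta2 and Gsta3, the 3 of 47 NRF2 and antioxidant genes that rose (5 rose and 2 fell adjusted over the list alone), with Gsta2 at 1.00 ± 0.14 and a camera adjusted p of 0.0672 for the list. Gsta1 was called in 10 of the 16 fits that left out 1 array. Gsta2 ranged from 0.375 to 1.175 over those fits and the alternatives. In the ciliated cell list 1 of 37 members, Tppp3 (called in 11 of the 16 fits), rose (13 adjusted over the list alone, camera adjusted p = 1.7e-09, adjusted p = 0.213 with an estimated correlation).

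In the B cell list 5 of 19 members rose (10 adjusted over the list alone), with a median of 0.64. Vpreb3, a gene of B cell precursors, rose by 0.94 ± 0.09 and Cd79b, of the B cell receptor, by 0.70 ± 0.13. Its camera adjusted p was 1.28e-07, and adjusted p = 0.213 with an estimated correlation and 0.038 with fry. In the T and NK cell list 3 of 35 members rose (10 adjusted over the list alone), namely Cd8b1 (0.95 ± 0.20), Lck and Cd5, with a camera adjusted p of 2.14e-09 and adjusted p = 0.28 with an estimated correlation. Of the 16 fits that left out 1 array, Lck was called in 4, Cd5 in 2 and Cd8b1 in 14. The list mean of 0.40 was -0.07 with normexp (camera adjusted p = 0.0885), where the median of all genes was -0.13. The macrophage list had 2 of 37 members higher (6 adjusted over the list alone), Mpeg1 and Csf1r, each called in 9 of the 16 fits, and 1 of the 2 other probes of Csf1r had the opposite sign (camera adjusted p = 4.54e-07, adjusted p = 0.204 with an estimated correlation). The MHC class II and dendritic cell list had 1 of 22 (6 adjusted over the list alone), Irf8 (camera adjusted p = 9.86e-05, adjusted p = 0.287 with an estimated correlation). Its mean of 0.26 was -0.05 with normexp, against -0.13 for the median of all genes (camera adjusted p = 0.0278). The interferon-stimulated list had 1 of 46 (1 adjusted over the list alone), Ifit3 at 0.89 ± 0.16 (camera adjusted p = 1.09e-07, adjusted p = 0.415 with an estimated correlation). Its mean was 0.58 in the slide of replicates 1 and 2 and 0.12 in the other, where it was not called (adjusted p = 0.0748). Of the cytokine list 3 members rose and 2, Areg and Cxcl15 (called in 3 and 2 of the 16 fits), fell (9 and 2 adjusted over the list alone), with Il33, an epithelial alarmin, at 0.48 ± 0.10 and the mucosal chemokine Cxcl17 at 0.72 ± 0.16 (camera adjusted p = 0.0118, adjusted p = 0.287 with an estimated correlation). Its mean of 0.17 was -0.21 with normexp and 0.04 in the slide of replicates 3 and 4 (adjusted p = 0.169).

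The erythroid list had 2 of 33 members lower, Klf1, a transcription factor of red cell precursors, at -0.99 ± 0.23, and Kel, called in 3 of the 16 fits (7 adjusted over the list alone, camera adjusted p = 0.000423, adjusted p = 0.52 with an estimated correlation). That list was no longer called without air replicate 2 of 24 h (adjusted p = 0.171) or in the slide of replicates 3 and 4 (adjusted p = 0.109). The cholesterol list had 1 of 27 lower (5 adjusted over the list alone), Tm7sf2 (camera adjusted p = 4.18e-08, adjusted p = 0.217 with an estimated correlation), and the matrix list 1 of 49 (5 adjusted over the list alone), Vcan at -0.43 ± 0.10, called in 9 of the 16 fits (camera adjusted p = 7.15e-06, adjusted p = 0.287 with an estimated correlation, 0.935 with normexp). None of 29 neutrophil genes was called by limma, over all genes or adjusted over the list alone, and the list median was -0.23 (camera adjusted p = 0.000555, adjusted p = 0.374 with an estimated correlation). The largest fall among called genes ranked by the naming rule was that of Nmrk2, a nicotinamide riboside kinase of muscle, at -1.72 ± 0.39. Cst8 and Galnt15 were higher by 1.16 ± 0.21 and 1.03 ± 0.17. Pln, a regulator of the calcium pump of muscle, was higher by 1.12 ± 0.25 but at -0.13 with normexp. Nmrk2, Klf1, Pln and Cd8b1 each lost the call without at least 1 array of 24 h, Cd8b1 without air replicate 3 or air replicate 4.

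Of the 59 genes taken by the naming rule and called at 24 h, 35 were called in every fit that left out 1 array. The count of 435 genes was 263 without air replicate 1, 271 without air replicate 2, 282 without air replicate 3, 266 without ozone replicate 3 and 271 without ozone replicate 4 of 24 h, 245 with Xist as a covariate and 1738 with array weights. With array weights 42.1% of the called genes were lower, against 65.7% in the main fit. With normexp 328 rose and 326 fell, and that correction moved the median of all genes from 0.02 to -0.13. With slide as a block 418 genes were called, and 47 and 255 within the slides. Of the 16 fits that left out 1 array, Klf1 and Nmrk2 were called in 10, Pln and Irf8 in 11 and Cxcl17 in 12.

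**Figure D2:**
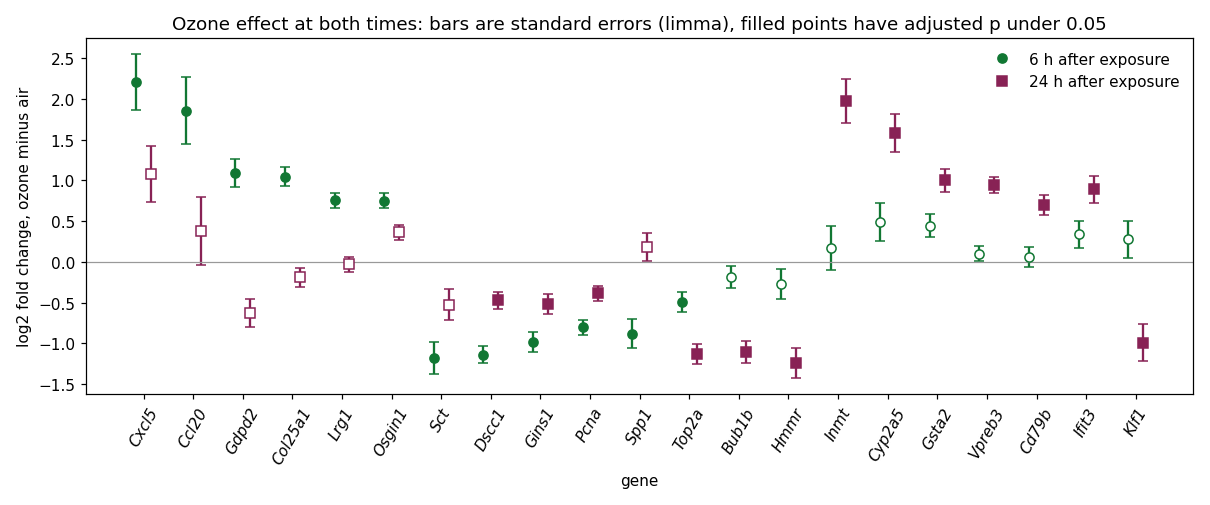
Log2 fold change of ozone against air for selected genes at 6 h (circles) and 24 h (squares) with limma standard errors, n = 4 per group, filled where the adjusted p was under 0.05. Cxcl5 stood at 2.21 at 6 h and Inmt at 1.98 at 24 h.

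Scan days and slides separated the times, so each ozone effect was taken against the air lungs of its own time. The ozone effect itself differed between the times for 14 genes, 10 more positive and 4 more negative at 24 h than at 6 h. Gdpd2 (1.09 at 6 h, -0.63 at 24 h), Col25a1 (1.04 and -0.19), the cyclin F gene Ccnf (0.29 and -0.81) and Lrg1 (0.76 and -0.03) were the more negative ones, with differences of -1.72 ± 0.25, -1.23 ± 0.17, -1.09 ± 0.18 and -0.79 ± 0.13 (adjusted p between 0.0217 and 0.0379). Prnd, Ms4a7, Batf3, a transcription factor of dendritic cells, Pifo and Mdh1b were the 5 largest in the other direction, between 0.86 and 0.99. Batf3 fell at 6 h by 0.67 ± 0.09 and was at 0.19 at 24 h. Among lists, mitosis had the most negative median difference, -0.67, with 1 of 45 members called and 39 adjusted over the list alone (camera adjusted p = 3.82e-33, adjusted p = 0.295 with an estimated correlation). The replication list had a median difference of 0.14 (camera adjusted p = 0.0159, adjusted p = 0.906 with an estimated correlation, 0.466 with quantile normalization), and no member was called, over all genes or adjusted over the list alone. Its call was lost without ozone replicate 2, air replicate 1 or air replicate 4 of 6 h, or without ozone replicate 1, ozone replicate 2, air replicate 1 or air replicate 2 of 24 h, with adjusted p between 0.0507 and 0.11. No list kept its call with an estimated correlation.

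The count of 14 was 6 with slide as a block, 38 with quantile normalization (17 more positive and 21 more negative), 547 with normexp (419 and 128) and 441 with array weights. It was 6, 5, 264, 7 and 0 without ozone replicate 2, ozone replicate 3, air replicate 2, air replicate 3 and air replicate 4 of 6 h, 1, 0, 7 and 5 without ozone replicates 1, 2, 3 and 4 of 24 h, and 0, 1 and 8 without air replicates 1, 2 and 4 of 24 h, and 2704 genes had an unadjusted p under 0.05 in the full fit of limma.

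Genes changed at both times overlapped more than independent lists would. Both contrasts share 1 estimate of each gene's spread, so the 2 lists are not fully independent. In all, 25 genes rose at both times, where 2.03 would be expected of independent lists (Fisher's exact test, two-sided p = 3.02e-20), and 91 fell at both, where 8.9 would be expected (p = 1.83e-66). Gins1, Pcna, Dscc1, Rrm2, Uhrf1, Cdk1, Top2a and Vcan fell at both times, as did Nmrk2 (-1.49 at 6 h), and Galnt15 and Cyp2b9 rose at both. One gene, Lrmda, was called in opposite directions. Across all genes, which are not independent replicates, the fold changes of the 2 times had a Pearson r of 0.043 and a Spearman rho of 0.10. The shared count of 116 was 75 without ozone replicate 2 and 51 without air replicate 4 of 6 h, 74 without ozone replicate 3 and 74 without air replicate 3 of 24 h, 38 with each time point fitted alone, 64 with Xist as a covariate and 379 with array weights.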

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

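The tests of erythroblast genes and of a lower share of another cell type were chosen only after the result was seen. The tests of other splits, sex, slide, control spots, receptor probes and thymus genes were written before their results were seen.

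Ozone replicate 3 of 6 h had more spots well above background than any other array, and its excess lay in dim genes, with a median deviation of 1.21 (log2) from its group in the 5407 dimmest genes and 0.02 in the 5408 brightest. Its negative control spots were not brighter, at -0.771% against the other ozone arrays of 6 h, which argues against optical background. Probes of olfactory and vomeronasal receptors, genes that no lung or chest tissue is known to express strongly, read higher on it by a median of 1.11. The rise was thus not confined to genes of such tissues. This passed the bound set beforehand for broad low signal from sequence the lung does not transcribe, such as genomic DNA or unspliced RNA. However, only 16.9% of these probes were well above background on the other ozone arrays of 6 h, so a rise like that of other dim genes was likely from the start. It therefore does not tell such signal apart from labelling or hybridisation of that array, and RNA of another tissue as an added source was not excluded. Without this array 433 genes were called at 6 h, and the mean of the replication list was -0.67.

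Replication genes were lower at 6 h, where the list call was lost with adjusted p = 0.0812 with an estimated correlation, and mitosis genes at 24 h, where it held (adjusted p = 0.0211). With Xist as a covariate the 2 list means kept at least 101% of their size, which argues against sex, and the list mean nearest 0 within a slide was -0.53, which argues against arrays of 1 slide. At 6 h the erythroid list, which was not called (camera adjusted p = 0.0834), had a median of 0.25 and 8 erythroblast genes one of 0.21, which argues against fewer red cell precursors in the lung as the source. Fewer such cells stay open at 24 h, where the erythroid list had a median of only -0.24 against -0.90 for mitosis and the 8 erythroblast genes one of -0.62. Of the 35 splits of the 8 arrays, 1, the real one, gave a list mean as far from 0 at 6 h (-0.62, highest other 0.47). At 24 h it was also 1, the real one (-0.89, highest other 0.60). These splits ignore the slides, and those that keep them are too few to exclude chance. A lower share of dividing cells in the lung after ozone, or slower division, is a candidate explanation that these data do not separate.

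At 24 h 5 of 19 B cell genes and 3 of 35 T and NK cell genes were higher, and the list calls were lost with adjusted p = 0.213 and adjusted p = 0.28 with an estimated correlation. The B cell median exceeded the endothelial one by 0.64, more than the SD of the endothelial genes (0.18). Alveolar type I and type II medians were 0.09 and 0.11, so the medians of these cell types did not rise alike. The B cell list was picked for its rise, and that SD is over genes rather than lungs. Whether a lower share of another cell type raised other types therefore stays open. With Xist as a covariate the B and T cell list means kept at least 71.4% of their size, which argues against sex as the whole cause. Thymus tissue in the dissected lung cannot be told apart, since 6 thymocyte genes had a median of 0.20 against 0.38 for the T and NK cell list, between the bounds set for it. The background treatment of dim probes also stays open, because with normexp the T and NK cell mean was -0.07 and the list was not called (camera adjusted p = 0.0885). The median of all genes was then -0.13.

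At 6 h, 1 of 35 splits of the arrays, the real one, called as many as 968 genes and the highest of the others called 181. At 24 h it was again 1 of 35, with 435 against 154. These splits ignore the slides, which carry structure of their own, so they do not exclude chance. In each case the highest other split was the one that followed the slides. Only 18 splits keep 2 arrays of each group on each slide, too few for a share under 0.05, and among them the real one called 968 against at most 52 at 6 h and 435 against 0 at 24 h. The highest other list means given above were from such balanced splits. For the difference between times, 4 of 100 drawn regroupings, the real one included, called at least 14 genes, and the highest other called 138. The regrouping that called 138 kept the real groups of 6 h, so it still held the ozone effect of that time. Those that called 84 and 50 followed the slides at 24 h and at 6 h, in that order. Of the 2 regroupings that kept the real groups of 6 h, 1 called 138 and the other 1, and the 7 that followed the slides at 1 time or more called between 0 and 84. For genes changed at both times in 1 direction, 1 of 100 regroupings, the real one, gave 116, and the highest other gave 0. Most other splits of either time called no gene, so a shared count of 0 was nearly fixed and adds nothing to the counts of each time.

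Single samples far from the other 3 of their group, by a gap larger than the critical share of the group's range in Dixon's test, were found in 17 of 394 groups tested, or 4.31%, where chance gives about 5%. Among lists these were B cell (0.937), endothelial (0.924) and macrophage and monocyte (0.873) in air at 24 h, metallothionein and metal handling (0.882) in air at 6 h, muscle (0.83) in ozone at 6 h and neutrophil (0.83) in ozone at 24 h. Among genes they were Ccl11 (0.899), Gins2 (0.968) and Xpc (0.899) in ozone at 6 h and Cd14 (0.876) in air at 6 h. At 24 h they were Csf1r (0.838), Gsta3 (0.91) and Inmt (0.927) in ozone, and Cdk1 (0.867), Kif15 (0.844), Kif4 (0.93) and Vpreb3 (0.916) in air.

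The ozone effect differed between times, by the test of the difference itself, for Gdpd2 (-1.72), Col25a1 (-1.23), Ccnf (-1.09), Lrg1 (-0.79), Nme9 (0.69), Ociad2 (0.72), Lrmda (0.81), Vpreb3 (0.84), Ddc (0.85), Mdh1b (0.86), Pifo (0.86), Batf3 (0.86), Ms4a7 (0.95) and Prnd (0.99). Nme9, Ociad2, Lrmda and Ddc were named after their values were seen. The lists called for the difference by camera, none of which held with an estimated correlation, had median differences of -0.67 (mitosis), 0.14 (DNA replication and S phase), -0.13 (acute phase), -0.33 (neutrophil), 0.37 (macrophage and monocyte), 0.34 (T and NK cell), 0.44 (B cell) and 0.28 (MHC class II and dendritic cell), the means of these last 3 being negative with normexp, 0.54 (interferon-stimulated), 0.22 (club cell), 0.32 (ciliated cell), -0.30 (fibroblast and extracellular matrix), 0.13 (heat shock and unfolded protein), -0.33 (erythroid) and 1.00 (adipose tissue). With normexp the median difference of all genes was itself -0.21, and the T and NK cell, B cell and MHC class II differences were not called (camera adjusted p between 0.135 and 0.769). The replication difference was lost with quantile normalization (adjusted p = 0.466) and without any 1 of 7 arrays (adjusted p between 0.0507 and 0.11). That of acute phase genes was lost with normexp (adjusted p = 0.747), with the mean of probes (adjusted p = 0.102) and without any 1 of 8 arrays (adjusted p between 0.0575 and 0.167). That of heat shock genes was lost with quantile normalization (adjusted p = 0.991) and without any 1 of 4 arrays (adjusted p between 0.0926 and 0.206). That of adipose genes was lost without air replicate 1 of 6 h (adjusted p = 0.0501) or ozone replicate 4 of 24 h (adjusted p = 0.0915), and that of fibroblast and matrix genes with normexp (adjusted p = 0.56).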

How the results depend on the processing

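The lists for replication at 6 h and mitosis at 24 h kept their direction in every alternative run. Their means ranged from -0.672 to -0.57 and from -0.959 to -0.814 when single arrays were left out, and replication at 6 h lost its call only with an estimated correlation (mean -0.618, adjusted p = 0.0812). The counts of genes moved more. In the order 6 h, 24 h, difference and both times, they were 247, 261, 1 and 45 with a replicate block, 1814, 1738, 441 and 379 with array weights, 1890, 714, 77 and 220 at an adjusted p under 0.1. With at least 1.5-fold they were 208, 247 and, at both times, 42, and with Xist as a covariate 558, 245 and 64. Leaving out 1 array gave 196 to 1690, 263 to 530, 0 to 264 and 51 to 121. Normexp gave 654 at 24 h and 547 for the difference, quantile normalization 38 and slide as a block 6 for the difference. Each time alone gave 100 at 6 h and 38 at both times. Contrasts within single slides gave 53 at 6 h and 47 and 255 at 24 h, with fewer arrays compared and the spread estimated over all slides. The number of called lists, 8 at 6 h, 18 at 24 h and 15 for the difference, was 0, 2 and 0 with an estimated correlation, 2, 7 and 0 with fry and 14 at 6 h with quantile normalization, and 8 to 13, 17 to 21 and 13 to 17 without 1 array. Fry called replication (adjusted p = 0.000308) and acute phase (0.0283) at 6 h. At 24 h it called mitosis (0.000233), replication (0.000971), club cell (0.00407), ciliated cell (0.0262), macrophage (0.0255), B cell (0.038) and thymus (0.0205). It did not call mitosis at 6 h (0.435) or interferon-stimulated genes at 6 h (0.472) or 24 h (0.177).

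Whether the replicate numbers used for that block pair the samples was checked on deviations of arrays from their group means. Same-numbered ozone and air arrays, which all shared a slide, correlated by 0.11 on average at 6 h and 0.111 at 24 h, and pairs of other numbers on 1 slide by 0.0652 and 0.238. Pairs on different slides correlated by -0.0886 and -0.174, so pairs on 1 slide were closer on average whether or not they shared a number. Not every same-numbered pair was above 0.1 (lowest 0.0505 and -0.00696), so the numbers were not taken to pair the samples. Because same-numbered arrays share a slide, the replicate block also removes differences between slides. With the replicate block the acute phase list also lost its call for the difference between times (camera adjusted p = 0.0632). Below, the sign of a value or list mean turned, or the direction of the test while the mean kept its sign (immediate early, heat shock difference, muscle). With normexp this held for Thsd7b at 6 h (0.12) and Pln at 24 h (-0.13), for list means at 24 h of cytokines (-0.213), T and NK cells (-0.066), MHC class II (-0.051), immediate early (0.017), heat shock (0.03) and thymus (-0.116), and for differences of NRF2 (0.022), T and NK cells (-0.339), B cells (-0.189) and MHC class II (-0.182). It held with quantile normalization for differences of alveolar type II cells (-0.055) and heat shock (0.029), for Thsd7b (0.15) with the mean of probes, and within 1 slide for hypoxia (-0.118) and ciliated cells (0.018) at 6 h and muscle (-0.024) at 24 h. Without single arrays ciliated cells at 6 h ranged from -0.098 to 0.013, turning without ozone replicate 2 of 6 h. Normexp also moved the median of all genes, to -0.13 at 24 h and -0.21 for the difference. The cause of these turns was not tested. Probes near background limit all values of dim genes.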

Other observations

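Tissues around the lung were also measured through their markers. At 24 h the adipose list had a median of 0.73, with 1 of 17 members called (2 adjusted over the list alone), Slc36a2 (camera adjusted p = 0.000153, adjusted p = 0.415 with an estimated correlation, 0.121 without ozone replicate 4 of 24 h, 0.437 in the slide of replicates 1 and 2), and the thymus and lymph node list 0.24, with Cd1d1, Cd8b1 and Ccl21a higher among 14 (5 adjusted over the list alone, camera adjusted p = 0.00083, adjusted p = 0.172 with an estimated correlation). The mean of the latter was -0.12 with normexp, where the median of all genes was -0.13 and the call was lost (adjusted p = 0.137). That call was also lost in the slide of replicates 1 and 2 (adjusted p = 0.272). The muscle list had a median of -0.24 at 24 h with 1 of 28 members, Pln, higher (1 adjusted over the list alone, camera adjusted p = 0.0415, adjusted p = 0.567 with an estimated correlation). The muscle list lost its call without air replicate 3 of 6 h, ozone replicate 1, ozone replicate 2, air replicate 2 or air replicate 3 of 24 h, with adjusted p between 0.0711 and 0.228, and also with normexp (adjusted p = 0.295) and in the slide of replicates 3 and 4 (adjusted p = 0.928). At 6 h none of 17 adipose, 14 thymus or 28 muscle genes was called over all genes (2 thymus genes were higher adjusted over the list alone), and none of 14 cartilage genes at either time.

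Of the lung cell lists, alveolar type I had 2 members higher (Sec14l3 and Cyp2b10, both also in the club cell list) and Igfbp2 lower (-0.77 ± 0.15) at 24 h among 31 (6 and 1 adjusted over the list alone, camera adjusted p = 0.0161, adjusted p = 0.52 with an estimated correlation), and Ahnak (called in 5 of the 16 fits that left out 1 array) higher at 6 h. The list was no longer called without air replicate 1 (adjusted p = 0.0798) or ozone replicate 4 (adjusted p = 0.0922) of 24 h or in the slide of replicates 3 and 4 (adjusted p = 0.464), with quantile normalization (adjusted p = 0.0797) or with the mean of probes (adjusted p = 0.177). Alveolar type II had Il33 higher and Scd1 and Cxcl15 (called in 10 and 2 of the 16 fits) lower at 24 h among 30, and none called at 6 h. None of 36 endothelial genes was called over all genes at either time, and 1 was higher at 24 h adjusted over the list alone. Of 22 smooth muscle genes, Hhip was lower at 6 h (-0.50 ± 0.11) and Pln higher at 24 h. None of 17 metallothionein and metal handling genes was called at either time, and the camera adjusted p was 0.359 at 6 h and 0.368 at 24 h. In the glucocorticoid and circadian list 1 of 36 members, Sult1a1, rose at 6 h (0.40) and 2 fell, Nr1d2 by 0.64 ± 0.12 and Dusp1 by 0.80 ± 0.20, while the list median was 0.14 (camera adjusted p = 0.359). At 24 h 1 member, Sgk1, fell by 0.59 ± 0.13 (camera adjusted p = 0.0800). Of 35 p53 targets, Xpc and Sesn2 (called in 11 and 12 of the 16 fits) rose at 6 h and Psrc1 fell at 24 h. Among 33 immediate early genes Gadd45b rose by 0.56 ± 0.12 and Dusp1 fell at 6 h, and none was called at 24 h. In the hypoxia and glycolysis list 2 of 33 members, Higd1a and Pgk1, fell at 6 h and none was called at 24 h. Of 22 mast cell, basophil and platelet genes, Gata2 rose at 6 h. Of the 16 fits, Gata2 was called in 10, Dusp1, Sgk1, Higd1a, Pgk1 and Ccl21a in 11, Sult1a1, Slc36a2 and Cd1d1 in 13, Hhip and Cyp2b10 in 14 and Gadd45b in 15. Among lists that camera did not call, the signs of the median, the mean and the test were not all alike for MHC class II, smooth muscle, p53, hypoxia and mast cell genes at 6 h, and for acute phase, p53 and immediate early genes at 24 h. The same held between times for NRF2, metallothionein, mucous, alveolar type II, p53, immediate early, mast cell and thymus genes.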
